A study of Mus musculus with 12 samples.

How the data were processed

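Total RNA was extracted with TRIzol from WAT of mice and from cultured adipocytes, and sequencing libraries were made with the MGIEasy mRNA kit, per the labels' protocols. Adipose tissue of WT and cKO mice and cultured adipocytes of WT and KO genotype formed 4 groups of 3 libraries, assigned from the sample titles. The authors deposited raw read counts per gene in 2 tables, 1 for WAT and 1 for the cultures, and these counts carry no normalization, as their whole values and unequal totals show. The submitters' processing notes name FastQC 0.11.2, cutadapt 1.11, HISAT2 2.1.0 and the genome build GRCm38 without saying what each was used for. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies therefore cannot be assigned with certainty.

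The WAT table lists 26639 features, of which 3137 are loci without a gene name. These took 0.416% to 0.832% of the counts of a library, and numbered copies of a symbol took 2.66% to 3.09%. The table of the cultures lists 22851 features, and 21669 symbols are in both. Mitochondrially encoded genes are listed for the cultures only, where they took 10.1% ± 1.72 (SD, n = 3) of counts in WT and 13.4% ± 2.05 in KO. All sample columns were used. Within each group the counts of any 2 libraries differed by more than sampling noise (chi-square per degree of freedom from 5.00 to 223), so no library was treated as a duplicate.

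Each comparison was fitted on its own 6 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr with a minimum count of 10 and scaling by TMM. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Adjusted p-values given for genes come from this test unless another tool is named. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic. Levels are CPM scaled by TMM factors. Biological coefficients of variation were 0.319 in WAT and 0.114 in culture. The difference between both effects was tested as an interaction over all 12 libraries and 14463 genes. The overlap of calls was set beside the product of the list sizes over the genes tested in both, with Fisher's exact test per direction, adjusted over the 4 directions.

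Gene lists, 29 in all, were fixed before the data were examined, together with the tests, the main alternatives and the rule for named genes. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists, beside camera with an estimated correlation and the directional test of fry. The rule named Fam50a and Fam50b, then the 6 largest rises and the 6 largest falls per comparison among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. Predicted or clone-named loci, pseudogenes, mitochondrial genes and immunoglobulin or T cell receptor segments were skipped. From each list it named the member with the smallest p, or the 3 smallest where the list passed, whether or not the member passed. It also named the 5 genes per direction changed in both comparisons the same way whose smaller change was largest, and the 5 genes per sign with the smallest interaction p. Some genes that the rule takes are not reported here. Krt8, Krt18, Myh4 and Siglecf were named after their values were seen. Coordinates are from the RefSeq annotation of GRCm38, and transcript lengths and GC content from the longest GENCODE transcript of each gene on that build.

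The alternatives were RLE size factors, no count filter, the replicate number as a block, each library left out in turn, 1 fit over all 4 groups, DESeq2 1.42.0, limma voom, a 2-fold minimum, and the list tests named above. Added after the data were seen were scaling by library size only, removal of a per-library trend with transcript length and GC content, summing of numbered copies, removal of unnamed loci, thinning of the culture libraries to the smallest total, and removal of mitochondrially encoded genes. The length and GC values covered 91.1% of genes tested in WAT and 98.0% in culture.

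The tests were tried on simulated counts drawn from the real means and library sizes with 200 changed genes. So few changed genes make the adjusted threshold stricter than in the data, where 8542 genes passed in WAT and 2459 in culture. The shares recovered in the simulations therefore do not measure recovery in the data. In the WAT simulation of 16293 genes edgeR recovered 0% of genes changed 1.5-fold, 13.4% of those changed 2-fold and 65.2% of those changed 4-fold, and 5.45% of its calls were unchanged genes, against 34.8% for DESeq2. DESeq2 recovered 46.3% of those changed 2-fold. In the culture simulation of 12587 genes edgeR recovered 55.2%, 85.1% and 95.5%, and 7.65% of its calls were unchanged genes, against 5.56% for DESeq2. In the interaction simulation of 14463 genes it recovered 2.99%, 19.4% and 75.8%, and 5.80% of its calls were unchanged genes. Its counts were drawn with the same shared spread, so it cannot show false calls that come from sharing it. Totals ran from 28844370 to 33997204 counts in WAT and from 10863158 to 21773610 in culture. Where all libraries of a group had 0 counts, the fold was computed against a floor of 3 counts over the group, which covers counting error only.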

Results

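Messenger RNA was sequenced in 12 libraries from mice that lack Xap5 in mature adipocytes and from their wild-type (WT) counterparts. Xap5 is a nuclear protein encoded in the mouse by Fam50a, and its deletion was driven by a Cre recombinase under the adiponectin promoter. White adipose tissue (WAT) was taken on postnatal day 42 from WT and conditional knockout (cKO) mice. Cultured adipocytes of WT and knockout (KO) genotype were taken on day 8 of adipogenic induction, after pre-adipocytes had been isolated from white fat of newborn animals. The 4 groups held 3 libraries each. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

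Total counts in WT WAT were 28844370, 30704234 and 30512141 for replicates 1 to 3, and those in cKO WAT were 33132906, 33146525 and 33997204. The WT cultures had 11601138, 11686881 and 12401278 counts. The KO cultures had 10863158, 21773610 and 21170115 counts, so that KO replicates 2 and 3 were sequenced more deeply than the other 4 culture libraries. The study asked how Xap5 bears on the development and death of adipocytes. For this question the knockout was compared with WT in tissue and in culture, and the difference between both effects was tested.

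Fam50a, the targeted gene, lies on chromosome X from 74313033 to 74320149 (GRCm38). Its level in WAT was 35.3, 32.5 and 36.5 CPM (read counts relative to library size, scaled by the trimmed mean of M-values, TMM) in WT replicates 1 to 3, and 23.3, 16.8 and 28.9 CPM in cKO replicates 1 to 3. The log2 fold change was -0.60 (standard error, SE, 0.20; adjusted p = 0.0395). With library size only the same change was 0.09 (adjusted p = 0.736), and with the length and GC trend removed it was -0.26 (adjusted p = 0.360). The call was also lost without WT replicate 1 (-0.59, adjusted p = 0.0916), 2 (-0.65, adjusted p = 0.0756) or 3 (-0.56, adjusted p = 0.108), and without cKO replicate 1 (-0.63, adjusted p = 0.0847). In culture, Fam50a was at 57.9, 52.0 and 45.2 CPM in WT and at 46.2, 42.9 and 41.1 CPM in KO replicates 1 to 3 (log2 fold change -0.26, SE 0.12, adjusted p = 0.134). It passed the threshold without WT replicate 3 (-0.34, adjusted p = 0.0258) and with the length and GC trend removed (-0.31, adjusted p = 0.0135). A count over the whole gene can include reads from outside the deleted part, and WAT holds cells that carry no active Cre, so these values neither bear out nor contradict the genotype labels. Fam50b, an autosomal retrocopy of Fam50a on chromosome 13 from 34734850 to 34747622, had 14, 34 and 10 reads in WT WAT and 0 reads in each cKO library. It was at least 34.4-fold lower in cKO WAT, with a floor of 3 counts over the group that covers counting error only (adjusted p = 0.0046). The bound was 21.6-fold without WT replicate 2 and 22.4-fold without cKO replicate 3. The cultures had 0 Fam50b reads in every library.

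**Figure D1:**
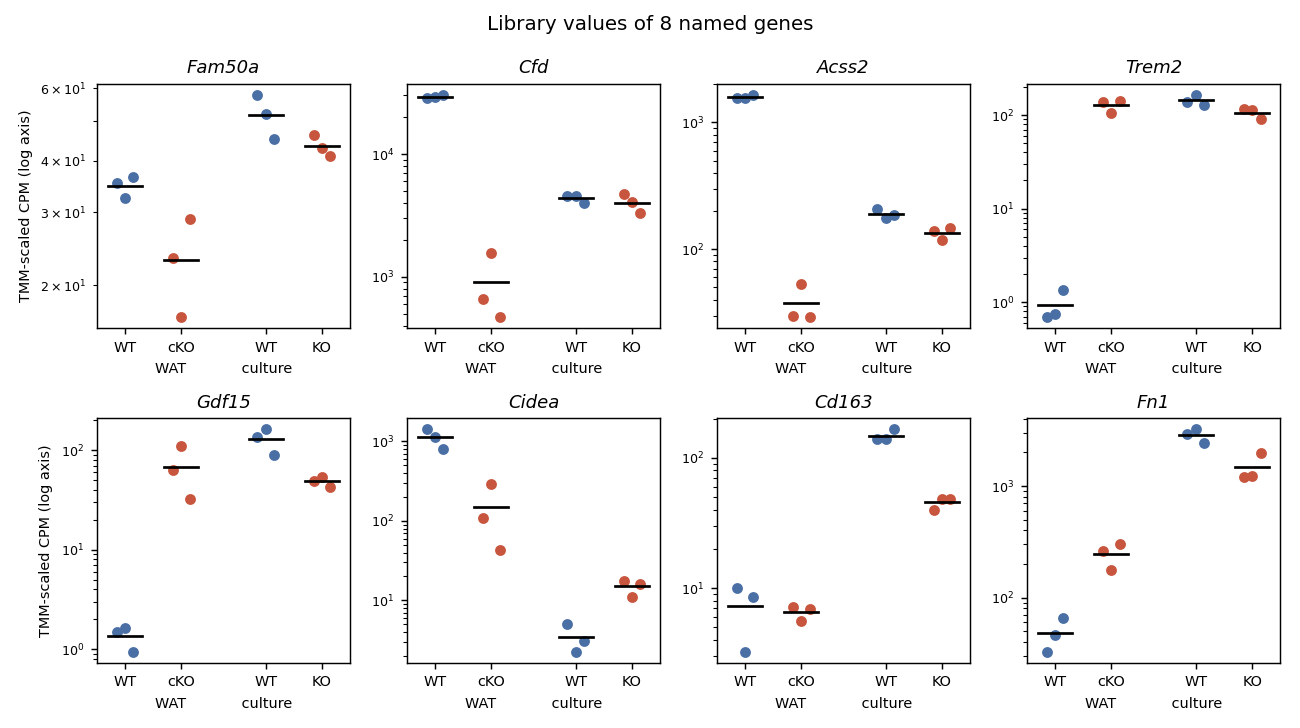
TMM-scaled CPM (log axis) of 8 named genes in each library of WAT and of cultured adipocytes, with WT in blue, knockout in red and the group mean as a line (n = 3 per group). Trem2 lay at 0.937 CPM in WT WAT and 128 CPM in cKO WAT on average, while Gdf15 was higher in cKO WAT and lower in KO cultures.

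In WAT at day 42, 23 of 24 genes of fatty acid and triglyceride synthesis fell in cKO and 21 of 24 macrophage markers rose. The calls of both lists were lost with an estimated correlation (adjusted p = 0.401 for each). Cfd, which encodes the adipocyte-secreted complement factor D, fell from 29387 ± 933 CPM (mean ± SD, n = 3) in WT to 904 ± 590 CPM in cKO WAT (log2 fold change -5.02, SE 0.56, adjusted p = 0.000804). Acss2, which forms acetyl-CoA from acetate, fell from 1587 ± 57.1 to 37.4 ± 13.6 CPM (-5.40, SE 0.30, adjusted p = 0.000347). Trem2, a lipid-sensing receptor of macrophages, rose from 0.937 ± 0.370 CPM to 137, 105 and 141 CPM in the cKO replicates (7.08, SE 0.30, adjusted p = 0.000136). Gdf15, a stress-induced secreted factor, rose from 1.35 ± 0.356 to 68.3 ± 38.7 CPM (5.65, SE 0.51, adjusted p = 0.000576).

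Of 16293 genes tested in WAT, 8542 changed, 4595 of them higher and 3947 lower in cKO. At least a 2-fold change was seen for 3158 of the higher and 1975 of the lower genes, 5133 in all. The 10 most abundant genes took 12.9% ± 0.343 (SD, n = 3) of counts in WT and 5.25% ± 0.287 in cKO WAT, and TMM factors averaged 0.790 and 1.27. Relative to TMM, scaling by library size only shifted the median log2 fold change of all genes by 0.68, and the split became 8838 higher against 1427 lower. With the length and GC trend removed it was 3197 higher against 4199 lower. Directions are given on the TMM scale, and a flip under library size only is named with the group it concerns.

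The largest rises after Mup18 were those of Atp6v0d2, a proton pump subunit of osteoclasts and macrophages (chromosome 4, 19876838 to 19922566; 8.46, SE 0.75), and Mmp12, the macrophage elastase (chromosome 9, 7344397 to 7360461; 7.35, SE 0.76). Vsig8 rose by 7.10 (SE 0.81). Mup18, a major urinary protein gene with close relatives whose reads it may share, had 0 reads in WT WAT and 28.5, 348 and 11.9 CPM in cKO replicates 1 to 3, at least 3071-fold higher with a floor of 3 counts over the group (adjusted p = 0.0104). This bound rested on cKO replicate 2, without which it was 479-fold, and it was 2036-fold without WT replicate 2 and 2026-fold without WT replicate 3. Second loci listed as Clic4-2 (7.13, SE 1.66) and Trem2-2 (7.12, SE 1.56) rose too, but cKO replicate 2 had 0.860 and 1.25 CPM of them, and reads could be split between such copies. limma voom called none of these 3, with adjusted p = 0.154 for Mup18, 0.430 for Clic4-2 and 0.386 for Trem2-2, and Clic4-2 also lost its call without WT replicate 2 (adjusted p = 0.0517). Slc2a5, a fructose transporter gene, fell by 8.31 (SE 0.84), and its second locus Slc2a5-2 fell by 9.28 (SE 0.86). Further large falls were those of Acsm3, a mitochondrial acyl-CoA synthetase gene (-7.31, SE 0.69), Kcng4 (-6.74, SE 0.64) and H2-Q10-3, a numbered copy of a histocompatibility gene (-6.92, SE 0.20).

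In the list for fatty acid and triglyceride synthesis, 23 of 24 measured members fell in cKO WAT (23 adjusted over the list alone) and 1 did not pass. Its median log2 fold change was -2.89 (camera adjusted p = 3.1e-22, adjusted p = 0.401 with an estimated correlation). Elovl6, a fatty acid elongase gene, fell by 5.20 (SE 0.31), and Slc25a1, the mitochondrial citrate carrier, fell by 4.70 (SE 0.40). Among mature adipocyte genes, 20 of 27 fell (21 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 2.5e-08, adjusted p = 0.401 with an estimated correlation). Dgat2, which completes triglyceride synthesis, fell by 2.73 (SE 0.36), and Gpd1, which supplies glycerol phosphate, fell by 2.64 (SE 0.35). For lipolysis and fatty acid oxidation, 19 of 25 members fell (20 adjusted over the list alone) and 1 rose, with a median of -1.52 (camera adjusted p = 1.6e-07, adjusted p = 0.401 with an estimated correlation). Acaa2 fell by 2.81 (SE 0.31) and Acadvl by 2.51 (SE 0.29), both enzymes of beta-oxidation, while Cpt1a, the liver-type carnitine palmitoyltransferase, rose by 1.77 (SE 0.19).

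All 34 measured nuclear-encoded respiratory chain subunits fell (34 adjusted over the list alone), with a median of -1.54 (camera adjusted p = 5.7e-16, adjusted p = 0.401 with an estimated correlation). Ndufb10 of complex I fell from 432 ± 20.3 to 128 ± 18.8 CPM, and Ndufs3 (-2.15, SE 0.28) and Sdha of complex II (-2.02, SE 0.27) fell as well. With library size only the median was -0.86 and 28 of the 34 fell. Of cholesterol synthesis genes, 20 of 24 fell (20 adjusted over the list alone) and 1 rose, with a median of -1.73 (camera adjusted p = 3.1e-15, adjusted p = 0.255 with an estimated correlation). Mvd (-2.74, SE 0.14), Fdft1 (-2.90, SE 0.18) and Dhcr7 (-2.13, SE 0.15), enzymes of that route, were among them. In the thermogenic list 11 of 19 fell (12 adjusted over the list alone) and 3 rose, with a median of -1.66 (camera adjusted p = 0.0215, adjusted p = 0.665 with an estimated correlation). Slc36a2 (-1.81, SE 0.33), Kcnk3 (-2.24, SE 0.43) and Prdm16 (-0.99, SE 0.19), all known from brown or beige fat, fell, and the call for Prdm16 was lost with library size only (-0.31, adjusted p = 0.174). Among factors that promote adipogenesis, 11 of 19 fell (12 adjusted over the list alone) and 4 rose, with a median of -0.78 (camera adjusted p = 0.0339, adjusted p = 0.401 with an estimated correlation). The balance of that list turned with library size only, to 7 higher and 5 lower with a median of -0.11. Rxra, the partner of PPARgamma, fell by 1.43 (SE 0.15) and Srebf1, a regulator of lipid synthesis, by 2.09 (SE 0.27). Creb1 rose by 1.29 (SE 0.17), a call that was lost with the length and GC trend removed (0.09, adjusted p = 0.717).

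Macrophage markers rose for 21 of 24 members (22 adjusted over the list alone), with a median of 2.72 (camera adjusted p = 5.6e-17, adjusted p = 0.401 with an estimated correlation). Msr1, a scavenger receptor (4.41, SE 0.30), Itgam, which encodes CD11b (4.16, SE 0.31), and Fcgr1, an antibody receptor (3.13, SE 0.24), were the clearest. Of markers of lipid-laden macrophages, 13 of 19 rose (13 adjusted over the list alone) and 2 fell (3 adjusted over the list alone), with a median of 2.60 (camera adjusted p = 1.4e-07, adjusted p = 0.401 with an estimated correlation). Gpnmb, a lysosomal glycoprotein gene of such cells, rose from 8.41 ± 3.46 to 952 ± 446 CPM. For neutrophil, eosinophil and mast cell markers, 9 of 13 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 2.94 that was the same with Siglecf, unread in WT WAT, set to its bound of at least 30.7-fold, or 20.3-fold without WT replicate 2 and 20.2-fold without WT replicate 3 (camera adjusted p = 0.00722, adjusted p = 0.401 with an estimated correlation). Mcpt4 (3.47, SE 0.35) and Cma1 (3.55, SE 0.39), mast cell proteases, rose, and Mmp9, a gelatinase of neutrophils, fell by 2.24 (SE 0.27). Preadipocyte and fibroblast markers rose for 11 of 20 and fell for 1 (11 and 1 adjusted over the list alone, 18 and 1 with library size only), with a median of 0.89 (camera adjusted p = 0.00334, adjusted p = 0.401 with an estimated correlation), including Lum (3.05, SE 0.33), Fap (2.36, SE 0.28) and Dcn (2.39, SE 0.29). Matrix genes rose for 20 of 29 (22 adjusted over the list alone) and fell for 3 (24 and 0 with library size only), with a median of 0.79 (camera adjusted p = 1.3e-05, adjusted p = 0.401 with an estimated correlation). Postn, a matricellular protein gene, rose by 4.04 (SE 0.34), Timp1, an inhibitor of metalloproteinases, by 2.61 (SE 0.25) and Loxl1, a crosslinking oxidase gene, by 1.20 (SE 0.11).

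Genes of cell division rose in cKO WAT for 26 of 28 members (26 adjusted over the list alone), with a median of 2.14 (camera adjusted p = 1.4e-10, adjusted p = 0.401 with an estimated correlation). Ccnb1 (3.21, SE 0.29), Top2a (2.79, SE 0.28) and Tpx2 (2.73, SE 0.28), all of mitosis, rose. Of p53 targets, 15 of 25 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.003, adjusted p = 0.401 with an estimated correlation). Mdm2, the ubiquitin ligase for p53, rose by 1.90 (SE 0.14) and Psrc1 by 2.75 (SE 0.30). In the list for necroptosis and pyroptosis, 8 of 21 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.78 that became 0.50 without WT replicate 1, and 18 rose and 0 fell with library size only (camera adjusted p = 0.0174, adjusted p = 0.401 with an estimated correlation). Casp1 (2.13, SE 0.24), Aim2 (3.67, SE 0.47) and Gsdmd (1.61, SE 0.23), genes of the inflammasome and of pyroptosis, were its members with the smallest p. Bulk RNA does not show which cells gave these reads, and macrophage markers rose in the same libraries. Inflammatory cytokine genes rose for 13 of 23 and fell for 2 (13 and 2 adjusted over the list alone, 18 and 0 with library size only), with a median of 1.47 (camera adjusted p = 0.00335, adjusted p = 0.401 with an estimated correlation). The chemokine genes Ccl9 (3.83, SE 0.32), Ccl6 (3.16, SE 0.32) and Cxcl2 (3.40, SE 0.45) rose. Interferon-stimulated genes rose for 19 of 28 (21 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 1.6e-06, adjusted p = 0.401 with an estimated correlation), led by Oas2 (3.17, SE 0.24), Ifit2 (2.74, SE 0.21) and Oasl1 (2.57, SE 0.25). In the antioxidant and ferroptosis list 13 of 26 fell and 6 rose (13 and 6 adjusted over the list alone), with a median of -0.56 that was 0.12 with library size only, where 6 fell and 11 rose (camera adjusted p = 0.00983, adjusted p = 0.401 with an estimated correlation). Gpx3, the secreted glutathione peroxidase, fell by 4.04 (SE 0.26) and Lpcat3 by 1.27 (SE 0.13), while Hmox1, heme oxygenase 1, rose by 2.09 (SE 0.21).

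Endothelial markers fell for 8 of 17 and rose for 1 (8 and 1 adjusted over the list alone), with a median of -0.47 that was 0.21 with library size only, where 1 fell and 4 rose (camera adjusted p = 0.029, adjusted p = 0.665 with an estimated correlation). Cldn5, a tight junction gene listed with a numbered copy, fell by 1.45 (SE 0.21). Cdh5 (-1.07, SE 0.22) and Tie1 (-0.95, SE 0.20) fell too, and both lost the call with library size only (-0.40, adjusted p = 0.132 and -0.28, adjusted p = 0.248). Schwann cell markers rose for 5 of 12 (3 adjusted over the list alone, 11 with library size only), with a median of 1.19 that became 2.01 without WT replicate 1 (camera adjusted p = 0.0321, adjusted p = 0.665 with an estimated correlation). Cdh19 (2.32, SE 0.47) and Mag (1.59, SE 0.48) rose. Mag lost the call without WT replicate 2 (adjusted p = 0.0786), WT replicate 3 (0.0875) or cKO replicate 1 (0.0757), and Cdh19 with the length and GC trend removed (0.0633).

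The 9 other lists did not pass in WAT (camera adjusted p from 0.0573 to 0.926). Regulators that restrain adipogenesis rose for 8 of 19 and fell for 1 (8 and 1 adjusted over the list alone, 14 and 0 with library size only), with Ddit3, which encodes CHOP, up by 2.01 (SE 0.27). Insulin signalling had 7 of 25 members lower and 4 higher (6 and 4 adjusted over the list alone), with a median of -0.15 that was 0.53 with library size only, where 5 were lower and 12 higher, among them Tsc2 (-1.20, SE 0.13). With the length and GC trend removed this list passed (median -0.65, adjusted p = 0.00562). Spliceosome components had 10 of 40 higher and 7 lower (10 and 7 adjusted over the list alone), among them Sf3b1 (1.16, SE 0.12), whose call was lost with the length and GC trend removed (0.20, adjusted p = 0.151). The spliceosome list passed with library size only (median 0.83 in place of 0.14, 31 higher and 3 lower, adjusted p = 0.0339). Apoptosis genes split into 7 higher and 7 lower of 29 (7 and 7 adjusted over the list alone), but into 19 higher and 1 lower with library size only (median 0.82 in place of 0.14). The clearest was Endog, a mitochondrial nuclease gene (-1.84, SE 0.15). Stress response genes split into 11 higher and 7 lower of 28 (11 and 7 adjusted over the list alone), but into 17 higher and 2 lower with library size only (median 0.78 in place of 0.096). Atf3, a stress-induced transcription factor gene, rose by 4.43 (SE 0.32). Lymphocyte markers rose for 3 of 22 (1 adjusted over the list alone, 6 with library size only), among them Cd22 (4.49, SE 0.45). Of skeletal muscle markers 1 of 19 rose (0 adjusted over the list alone), Myh1, which overlapped between groups at 0, 0.709 and 0.620 CPM in WT and 54.4, 5.53 and 0.498 CPM in cKO replicates 1 to 3. Its call was lost without any one of WT replicates 1, 2 and 3 (adjusted p = 0.0936, 0.0967 and 0.0889) or cKO replicate 1 (0.146), by limma voom (0.380) and with the replicate block (0.197). Erythroid markers rose for 1 of 8 (0 adjusted over the list alone). The median, mean and camera direction differed in sign for the lymphocyte, skeletal muscle and erythroid lists, whose medians of -0.16, -0.12 and -0.17 turned to 0.52, 0.56 and 0.51 with library size only.

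Epithelial markers had a median of 3.83 over 11 measured members with 1 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.926), and this value came from 1 library. Krt8, Krt18, Myh4 and Siglecf were named after their values were seen. Krt8 was at 209 CPM and Krt18 at 222 CPM in cKO replicate 3, whereas Krt18 was at 0 to 11.1 CPM in the other 5 WAT libraries. Without cKO replicate 3 the median turned to -3.09 (camera adjusted p = 0.0296). Trp63, a basal epithelial transcription factor gene, was the member that fell (-2.10, SE 0.64, adjusted p = 0.028), and its call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0523, 0.0519 and 0.0969), without cKO replicate 1 or 2 (0.0698 and 0.067) and with library size only (0.0947). Muscle transcripts varied within both groups, with Myh4 at 0, 12.9 and 284 CPM in WT and 198, 11.8 and 1.43 CPM in cKO replicates 1 to 3.

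In WAT, 20 of 29 lists passed by camera with a preset correlation, and 18 passed by fry. The same camera test passed 7 to 18 lists in splits of these libraries that mix the genotypes. With an estimated correlation camera called 0 lists at adjusted p, and 2 at an unadjusted p under 0.05. The factors that promote adipogenesis lost their call without WT replicate 1 (adjusted p = 0.0893) or cKO replicate 3 (0.0519), in 1 fit over all 4 groups (0.062) and with the length and GC trend removed (0.0508). Endothelial markers lost theirs without WT replicate 3 (0.0579), cKO replicate 2 (0.0797) or cKO replicate 3 (0.0928). The Schwann cell markers did so without WT replicate 2 (0.0568), WT replicate 3 (0.0681) or cKO replicate 2 (0.0964) and in 1 fit over all 4 groups (0.0896). By fry the thermogenic list (0.0846), the endothelial markers (0.0767) and the Schwann cell markers (0.0566) did not pass. The endothelial (0.103), Schwann cell (0.111) and granulocyte and mast cell markers (0.0711) did not pass by camera with library size only.

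**Figure D2:**
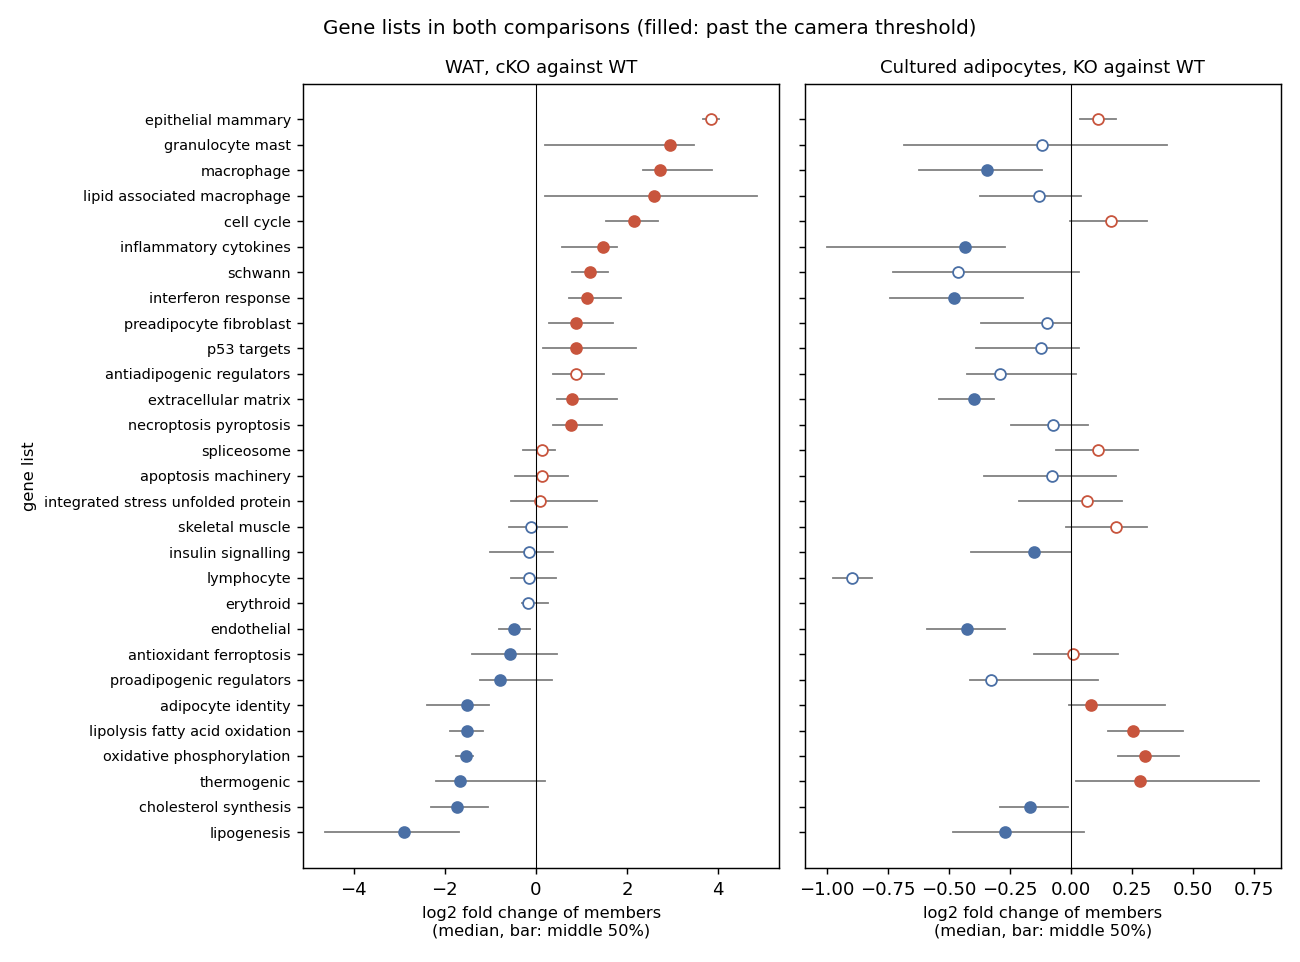
Median log2 fold change (points) and middle 50% (bars) of the measured members of each gene list in WAT (left) and cultured adipocytes (right), on different axis ranges, with filled points where camera passed and colour giving the sign. Lipogenesis had the lowest median in WAT at -2.89 and was at -0.27 in culture, and with library size only the endothelial, antioxidant, insulin signalling, lymphocyte, skeletal muscle and erythroid medians in WAT turned to 0.21, 0.12, 0.53, 0.52, 0.56 and 0.51, and the antioxidant median in culture to -0.050.

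In cultured adipocytes, 12 of 24 macrophage markers, 15 of 23 inflammatory cytokine genes and 20 of 29 matrix genes fell in KO, while 1, 0 and 2 rose. The calls of these lists were lost with an estimated correlation (adjusted p = 0.363 for each). The matrix median of -0.40 was -0.17 with the length and GC trend removed. Cd163, a scavenger receptor of resident macrophages, fell from 148 ± 14.8 CPM (mean ± SD, n = 3) in WT to 45.4 ± 5.03 CPM in KO (log2 fold change -1.70, SE 0.12, adjusted p = 1.5e-09). Fn1, which encodes fibronectin, fell from 2849 ± 384 to 1469 ± 438 CPM (-0.96, SE 0.15, adjusted p = 0.000227). Fabp4, the adipocyte fatty acid binding protein, rose from 8032 ± 652 to 14930 ± 1855 CPM (0.89, SE 0.13, adjusted p = 7.0e-05). Cidea, a lipid droplet protein gene abundant in brown fat, rose from 3.48 ± 1.44 to 15.0 ± 3.55 CPM (2.09, SE 0.24, adjusted p = 2.7e-06).

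Of 12587 genes tested in culture, 2459 changed, 1125 of them higher and 1334 lower in KO. At least a 2-fold change was seen for 56 of the higher and 132 of the lower genes, 188 in all. With library size only the split was 786 higher against 1765 lower. In 1 fit over all 4 groups, which shares the wider spread of WAT, 146 genes changed, and 57 of the genes named here for culture lost their call. The count was 897 without WT replicate 2, 1499 without WT replicate 1, 1528 without KO replicate 1 and 1511 without KO replicate 2.

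Besides Cidea, the largest rises in culture were those of Cyp2e1, a cytochrome P450 gene (chromosome 7, 140763819 to 140774990; 1.80, SE 0.16), Sirt3, the mitochondrial deacetylase (chromosome 7, 140863663 to 140882309; 1.71, SE 0.12), Rps27a, a ribosomal protein gene with many pseudogenes that can share its reads (1.62, SE 0.21), Sarnp (1.51, SE 0.25) and Scg2, a secretogranin gene (1.44, SE 0.17). The largest falls were those of Alox5, which encodes 5-lipoxygenase (-2.05, SE 0.21), Marco, a macrophage scavenger receptor (-1.76, SE 0.12), Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages (-1.75, SE 0.16), Ugt1a6b, a glucuronosyltransferase gene that shares exons with its family (-1.68, SE 0.23), and Entpd4b (-1.78, SE 0.40). Entpd4b had the same counts as Entpd4 in every culture library, so the 2 copies cannot be told apart there, and DESeq2 did not call it (adjusted p = 0.164).

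In the adipocyte list 9 of 26 measured members rose and 3 fell in culture (9 and 3 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.00981, adjusted p = 0.365 with an estimated correlation). Pparg, the master regulator of adipogenesis, rose by 0.52 (SE 0.11), and Adipoq, which encodes adiponectin (chromosome 16, 23146536 to 23157968), rose by 0.47 (SE 0.11). Genes of lipolysis and fatty acid oxidation rose for 9 of 25 (12 adjusted over the list alone) and fell for 2, with a median of 0.26 (camera adjusted p = 0.000199, adjusted p = 0.365 with an estimated correlation). Etfa (0.55, SE 0.12), Etfb (0.61, SE 0.13) and Decr1 (0.52, SE 0.11), which serve beta-oxidation, rose. Respiratory chain subunits rose for 17 of 34 (22 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 3.9e-09, adjusted p = 0.365 with an estimated correlation). Ndufa5 rose by 0.72 (SE 0.11), Cox6b1 by 0.56 (SE 0.11) and Ndufb3 by 0.51 (SE 0.11), and the call for Ndufb3 was lost with the length and GC trend removed (0.16, adjusted p = 0.156). With that trend removed the list's median was 0.19, over 1.5 times smaller, and its camera adjusted p was 4.1e-05. In the thermogenic list 4 of 12 rose (5 adjusted over the list alone, which also gave 1 that fell), with a median of 0.28 (camera adjusted p = 0.00485, adjusted p = 0.363 with an estimated correlation). Cox8b (0.90, SE 0.16) and Pank1 (0.73, SE 0.22) rose, and Pank1 lost its call without WT replicate 2, KO replicate 1 or KO replicate 2 (adjusted p = 0.0806, 0.0621 and 0.0728).

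Genes of fatty acid and triglyceride synthesis fell for 10 of 24 (11 adjusted over the list alone) and rose for 2, with a median of -0.27 (camera adjusted p = 0.00981, adjusted p = 0.389 with an estimated correlation). Scd2 (-0.69, SE 0.13) and Fads2 (-0.59, SE 0.12), both desaturases, and Fasn, fatty acid synthase (-0.63, SE 0.13), fell. With the length and GC trend removed the list's median was -0.12 (adjusted p = 0.173) and Fasn was at -0.16 (adjusted p = 0.255). Cholesterol genes fell for 5 of 24 (5 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0258, adjusted p = 0.363 with an estimated correlation). Insig1 (-0.69, SE 0.12) and Srebf2 (-0.55, SE 0.11), regulators of sterol synthesis, fell, and the call for Srebf2 was lost with the length and GC trend removed (-0.21, adjusted p = 0.0557). Insulin signalling genes fell for 7 of 25 and rose for 1 (7 and 1 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0493, adjusted p = 0.422 with an estimated correlation). Irs2, an insulin receptor substrate (-0.96, SE 0.13), and Igf1r (-0.55, SE 0.14) fell, and Pde3b, an antilipolytic phosphodiesterase, rose by 0.49 (SE 0.11). Igf1r lost its call with the length and GC trend removed (-0.26, adjusted p = 0.138) and Pde3b without WT replicate 2 (adjusted p = 0.0513). The call of the insulin list ended with that trend removed (median -0.0027, adjusted p = 0.842), with RLE size factors (-0.15, adjusted p = 0.0505), with thinned libraries (-0.16, adjusted p = 0.0565) and without mitochondrially encoded genes (-0.14, adjusted p = 0.0529).

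Macrophage markers in the cultures fell for 12 of 24 (14 adjusted over the list alone) and rose for 1, with a median of -0.34 (camera adjusted p = 1.2e-07, adjusted p = 0.363 with an estimated correlation). Laptm5 (-0.84, SE 0.13) and C1qa, a complement subunit (-0.75, SE 0.12), fell. Inflammatory cytokine genes fell for 15 of 23 (16 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.2e-11, adjusted p = 0.363 with an estimated correlation). The chemokine genes Ccl6 (-1.02, SE 0.11), Ccl3 (-1.32, SE 0.15) and Ccl8 (-0.98, SE 0.13) fell. Interferon-stimulated genes fell for 12 of 28 (15 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 4.2e-06, adjusted p = 0.389 with an estimated correlation) that became -0.27 without WT replicate 2. Oasl1 (-1.04, SE 0.19), Oas1a (-0.80, SE 0.16) and Bst2 (-0.58, SE 0.12) fell, the last not past the threshold without WT replicate 2 (adjusted p = 0.064). Matrix genes fell for 20 of 29 (23 adjusted over the list alone) and rose for 2 (3 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 6.5e-08, adjusted p = 0.363 with an estimated correlation). With the length and GC trend removed this median was -0.17 (camera adjusted p = 0.000986). Mmp3 (-0.82, SE 0.13) and Col6a3 (-0.82, SE 0.15) fell beside Fn1. Endothelial markers fell for 6 of 17 (9 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 2.8e-05, adjusted p = 0.363 with an estimated correlation) that became -0.27 without WT replicate 2. Vwf, von Willebrand factor (-1.33, SE 0.18), Cdh5 (-0.64, SE 0.12) and Robo4 (-0.84, SE 0.17) fell.

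The other 16 lists with measured members did not pass in culture (camera adjusted p from 0.0594 to 0.934), and the erythroid list had 0 measured members there. Factors that promote adipogenesis fell for 6 of 19 and rose for 2 (10 and 3 adjusted over the list alone), among them Cebpb, an early adipogenic factor gene (-1.40, SE 0.29), which DESeq2 did not call (adjusted p = 0.119). Factors that restrain it fell for 3 of 16 and rose for 1 (4 and 1 adjusted over the list alone), Ddit3 (0.52, SE 0.13). Spliceosome components rose for 8 of 40 and fell for 1 (8 and 2 adjusted over the list alone, 4 and 3 with library size only), among them Snrpd1 (0.51, SE 0.11), whose call was lost with the length and GC trend removed (0.12, adjusted p = 0.309). Cell division genes rose for 2 of 28 (0 adjusted over the list alone), among them Cdk1 (0.41, SE 0.12), lost without WT replicate 2 (adjusted p = 0.0937), KO replicate 1 (0.0713) or KO replicate 2 (0.0755). Of p53 targets 4 of 23 fell and 1 rose (5 and 1 adjusted over the list alone), and Gdf15 fell by 1.40 (SE 0.15). Of stress response genes 5 of 28 fell and 2 rose (5 and 2 adjusted over the list alone), with Ddit4, an inhibitor of mTOR signalling, at -1.01 (SE 0.13). In the necroptosis and pyroptosis list 3 of 20 fell and 1 rose (3 and 1 adjusted over the list alone), and Ninj1, which ruptures the plasma membrane of dying cells, was at -0.61 (SE 0.13). Apoptosis genes rose for 4 of 28 and fell for 3 (4 and 5 adjusted over the list alone, and 4 and 5 with library size only), and Aifm1, apoptosis-inducing factor, was at 0.67 (SE 0.11). In the antioxidant list 5 of 26 fell and 2 rose (5 and 4 adjusted over the list alone), with Hmox1 at -0.52 (SE 0.11). The median, mean and camera direction of the apoptosis and stress response lists were not all of 1 sign. The antioxidant median of 0.0065, with a fry direction down, was -0.050 with library size only.

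Lipid-laden macrophage markers fell for 5 of 18 (5 adjusted over the list alone, which also gave 1 that rose), among them Ctsd, a lysosomal protease gene (-0.60, SE 0.12). Their median of -0.13 became -0.30 with the length and GC trend removed, and the list then passed (adjusted p = 4.1e-05). Preadipocyte and fibroblast markers fell for 5 of 18 and rose for 1 (6 and 1 adjusted over the list alone), with Pdgfrb at -0.50 (SE 0.12), lost without WT replicate 2 (adjusted p = 0.0718) and with the length and GC trend removed (0.0899). Schwann cell markers fell for 2 of 7 (3 adjusted over the list alone), with Sox10 at -1.05 (SE 0.28), lost without WT replicate 2 (adjusted p = 0.0833). Of granulocyte and mast cell markers 1 of 4 fell, Mmp9 (-1.20, SE 0.26; 1 fell and 1 rose adjusted over the list alone). Lymphocyte markers had 2 measured members, of which Cd22 fell (-0.74, SE 0.23; 2 adjusted over the list alone), a call lost without WT replicate 1 or 2 (adjusted p = 0.0961 and 0.0999) or KO replicate 2 or 3 (0.073 and 0.0867) and with the length and GC trend removed (0.0503). Of muscle markers 1 of 8 rose, Mb, which encodes myoglobin (1.09, SE 0.20; 1 adjusted over the list alone). Epithelial markers had 2 measured members and 0 past the threshold (0 adjusted over the list alone), with Trp63 at 0.26 (SE 0.38, adjusted p = 0.675).

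In culture 12 lists passed by camera with a preset correlation and 13 by fry, and with an estimated correlation camera called 0 at adjusted p and 1 at an unadjusted p under 0.05. Splits of the culture libraries that mix the genotypes passed 4 to 9 lists by camera with the preset correlation. Calls were lost without WT replicate 3 for the adipocyte list (median 0.14), the thermogenic list (0.16) and cholesterol genes (-0.17, adjusted p = 0.061 for each of these 3) and insulin signalling (-0.16, adjusted p = 0.139). The same held without KO replicate 2 for lipogenesis (-0.19) and cholesterol genes (-0.08, adjusted p = 0.0849 for both) and without KO replicate 1 for insulin signalling (-0.11, adjusted p = 0.186). Further calls were lost in 1 fit over all 4 groups for the adipocyte, lipogenesis and thermogenic lists (adjusted p = 0.0914, 0.0719 and 0.302), and by fry for lipogenesis, the thermogenic list, lipolysis, insulin signalling and interferon-stimulated genes (0.0789, 0.0521, 0.0504, 0.107 and 0.107).

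The effect of the knockout differed between tissue and culture for 7061 of 14463 genes in a test of the difference itself, 4009 of them more positive and 3052 more negative in WAT. With library size only these were 7331 and 1198. The fit behind this test shares 1 spread per gene between WAT and culture, which can understate that of WAT. It called 9005 genes in WAT, against 8542 in the fit of WAT alone. WAT and cultures also differed in stage, in the cells present and in the features counted. The counts do not show how far the deletion went in either. None of these can be told apart here from a different effect of the knockout on the same cells. Trem2 was the gene with the smallest p on the positive side (difference of log2 fold changes 7.55, SE 0.30), followed by Ifi204, an interferon-inducible gene (3.55, SE 0.21), Pla2g4a, a phospholipase gene (3.85, SE 0.24), Tlr13, a receptor for bacterial RNA (5.82, SE 0.39), and Lilrb4a, an inhibitory receptor of myeloid cells (4.76, SE 0.32). On the negative side stood Ntrk2, a neurotrophin receptor gene (-3.63, SE 0.17), Hsd11b1, which regenerates glucocorticoids (-5.68, SE 0.30), and Acss2 (-4.87, SE 0.29). Of 29 lists, 17 differed between tissue and culture by camera and 0 with an estimated correlation, where the smallest adjusted p was 0.0566 for cholesterol genes. Macrophage markers were more positive in WAT by a median of 3.23 (camera adjusted p = 3.0e-22, adjusted p = 0.169 with an estimated correlation). Lipogenesis (-2.84) and respiratory chain genes (-1.81) were more negative (camera adjusted p = 1.8e-21 for both, adjusted p = 0.169 and 0.213 with an estimated correlation).

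Among 12343 genes tested in both comparisons, 589 changed in both the same way and 845 in opposite ways. Higher in both were 269 genes, against 341 for independent lists (Fisher's exact test, adjusted p = 1.2e-06), and lower in both were 320, against 362 (adjusted p = 0.00665). Higher in WAT and lower in culture were 466, against 403 (adjusted p = 0.000114), and the reverse held for 379, against 306 (adjusted p = 1.2e-06). With library size only, 410 genes were higher in both, 149 were lower in both and 1193 changed in opposite ways. Genes are not independent replicates, so the p-values of Fisher's exact test do not measure the spread between samples. The correlation of log2 fold changes across genes, to which the same limit applies, was -0.10 (Pearson) and -0.09 (Spearman). The balance of same-way and opposite calls rested on 1 library. Without WT culture replicate 3 there were 1036 genes changed the same way, against 972 for independent lists, and 937 in opposite ways. With no count filter 619 changed the same way, against 628 for independent lists, and 903 in opposite ways. Without other culture libraries fewer genes were called in culture, and fewer changed the same way. These were 263 without WT replicate 1, against 425 for independent lists, and 187 without WT replicate 2, against 251. They were 381 without KO replicate 1, against 431, and 333 without KO replicate 2, against 428.

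Genes higher in both included Zfp949, a zinc finger gene (1.13, SE 0.21 in WAT and 1.37, SE 0.18 in culture), Fcrls, a receptor gene of microglia and some macrophages (1.02, SE 0.26 and 1.01, SE 0.16), Hnrnpa3, an RNA-binding protein gene (1.10, SE 0.13 and 0.84, SE 0.29), Rpl17, a ribosomal protein gene (0.88, SE 0.28 and 0.84, SE 0.20), and Srp54b, a copy of the signal recognition particle gene Srp54a (0.78, SE 0.21 and 1.07, SE 0.32). In culture Hnrnpa3 was at 0.28 (adjusted p = 0.544), Rpl17 at 0.34 (adjusted p = 0.0995) and Srp54b at 0.60 (adjusted p = 0.183) without KO replicate 2, and the WAT values of Hnrnpa3 (0.01, adjusted p = 0.937) and Srp54b (0.06, adjusted p = 0.770) were lost with the length and GC trend removed. DESeq2 did not call Hnrnpa3, Rpl17 or Srp54b in culture (adjusted p = 0.318, 0.124 and 0.243). There limma voom did not call Hnrnpa3 (0.0756) or Srp54b (0.162). The culture calls of Hnrnpa3 (0.089) and Srp54b (0.0782) ended with the length and GC trend removed, as did the WAT call of Rpl17 (0.0669). That of Hnrnpa3 in culture also ended with library size only (0.0543) and with thinned libraries (0.0524). Without single culture libraries the calls were also lost for Hnrnpa3 (WT replicate 2, adjusted p = 0.205, and WT replicate 3, 0.0763) and Srp54b (KO replicate 1, adjusted p = 0.0854, and WT replicate 3, 0.103). In WAT, Fcrls lost its call without WT replicate 2 (adjusted p = 0.0619), Srp54b without WT replicate 3 (0.0518) or cKO replicate 1 (0.0528), and Rpl17 without WT replicate 2 or 3 (0.123 and 0.112) or cKO replicate 1 or 3 (0.0791 and 0.0914). Summed over Srp54a, Srp54b and Srp54c, the change was 0.72 (SE 0.19) in WAT and 0.68 (SE 0.15) in culture. Genes lower in both included Entpd4b (-1.92, SE 0.25 in WAT), Cebpb (-1.69, SE 0.38), Sorl1, a sorting receptor gene (-2.02, SE 0.42 in WAT and -1.12, SE 0.24 in culture), Cspg4, which encodes NG2 (-2.53, SE 0.40 and -1.09, SE 0.16), and Ddit4 (-1.71, SE 0.18 in WAT). Summed over Entpd4 and Entpd4b, the change was -1.88 (SE 0.27) in WAT and -1.78 (SE 0.40) in culture.

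**Figure D3:**
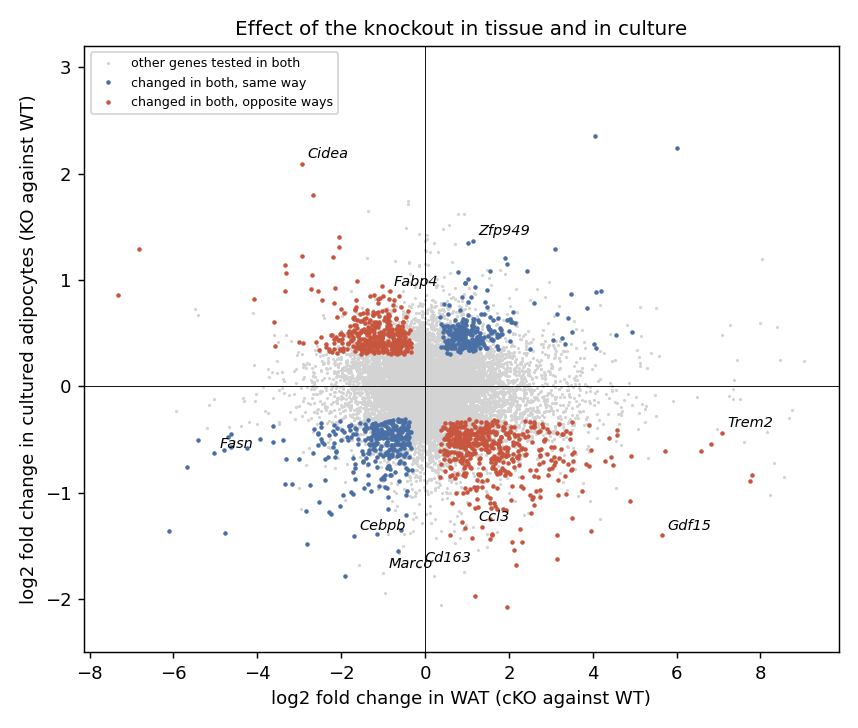
Log2 fold change in WAT (horizontal axis) against that in cultured adipocytes (vertical axis) for 12343 genes tested in both, with genes changed in both the same way in blue and in opposite ways in red. The 589 blue and 845 red genes stand against 703 genes changed the same way for independent lists, and the names mark examples.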

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

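The tests of the scaling of the libraries, of a lower adipocyte share, and of the Adipoq neighbourhood, its chance neighbours and its overlapping gene models were chosen only after the results were seen. So were the settings with the length and GC trend removed and with thinned libraries.

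Genes whose change between genotypes differed between WAT and culture by the interaction test numbered 7061. Stage, the cells present and the extent of deletion cannot be told apart from the response to the knockout in this count. The named genes more positive in WAT were Trem2 (7.55, adjusted p = 3.0e-08), Ifi204 (3.55, adjusted p = 8.3e-07), Pla2g4a (3.85, adjusted p = 1.3e-06), Tlr13 (5.82, adjusted p = 2.0e-06) and Lilrb4a (4.76, adjusted p = 2.1e-06). Those more negative in WAT were Ntrk2 (-3.63, adjusted p = 9.3e-08), Hsd11b1 (-5.68, adjusted p = 2.9e-07) and Acss2 (-4.87, adjusted p = 8.3e-07). These calls held in every alternative run for the interaction, all of which share 1 spread per gene between WAT and culture. Of 134 other named genes with an interaction test, 101 differed as well, and 5 had no test. Over all genes tested 7061 of 14463 differed. Most named genes were taken for their change or p in WAT or in culture, which favours a difference, so their share adds no support. Of 100 assignments of genotype within WAT and within culture, drawn from 200, 1 gave as many as 7061 genes, the real one. Another 10 kept WAT split by genotype with the cultures mixed and reached up to 6838, so counts nearly as high did not need the real culture split. Assignments without the WAT split mix its genotypes within groups, which widens the spread and holds the count down. Their highest count of 1 therefore cannot tell whether chance gave the 7061.

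Lists that differed by camera (adjusted p from 3.0e-22 to 0.0425) were the adipocyte genes (median -1.73), lipogenesis (-2.84), lipolysis and oxidation (-1.73), thermogenic genes (-1.28), respiratory chain genes (-1.81), cholesterol synthesis (-1.52) and antioxidant genes (-0.66) on the negative side. On the positive side were factors that restrain adipogenesis (1.26), macrophage markers (3.23), lipid-laden macrophage markers (3.01), preadipocyte and fibroblast markers (1.17), matrix genes (1.47), necroptosis and pyroptosis genes (0.91), p53 targets (0.80), inflammatory cytokine genes (2.13), interferon-stimulated genes (1.56) and cell division genes (2.12). None passed with an estimated correlation, where adjusted p ran from 0.0566 to 0.574.

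In cKO WAT 23 of 24 fat synthesis genes fell, a list call that was lost with an estimated correlation (adjusted p = 0.401). The fall did not rest on the choice between TMM and library size only, since 20 of 24 lipogenesis members were still lower past the threshold with the latter. Both scalings are relative to the counts of the library, so a change in the amount of RNA was not tested. A lower share of adipocytes alone would lower a gene read from adipocytes by at most as much as Adipoq (-2.12, SE 0.42), if Adipoq only follows that share, but the ratio to Adipoq in the same library was lower in cKO for 11 of 24 lipogenesis members and higher for 1 (limma, adjusted over the list). By limma the same ratio was lower for 2 and higher for 7 of 26 adipocyte genes, lower for 0 and higher for 4 of 25 lipolysis and oxidation genes, 0 and 6 of 24 cholesterol synthesis genes and 0 and 0 of 34 respiratory chain genes (0 and 9, 1 and 8, and 0 and 8 at an unadjusted p under 0.05), so for the last 3 lists and most adipocyte genes a lower share stays open. A candidate explanation for the synthesis genes is a change within the remaining adipocytes, alone or with a loss of such cells, and bulk RNA cannot separate these.

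In KO cultures respiratory chain genes were higher and matrix genes lower by camera with a preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.365 and 0.363). Fold changes fell with GC content in culture (Spearman correlation across genes -0.34) and in WAT (-0.30). With transcript length they fell in culture (-0.26) and rose in WAT (0.23). With the length and GC trend removed the respiratory chain median in culture was 0.19 in place of 0.30. The list was still past the threshold with the preset correlation, so this trend may account for part of the change. Whether it accounts for all of it cannot be told, since the correction used the longest transcript of each gene and may leave some trend behind. The matrix median went from -0.40 to -0.17, under 50% of its size, so the trend is a candidate source of most of that change, although the list stayed past the same threshold (camera adjusted p = 0.000986). Thinning to the smallest total left medians of 0.31 and -0.40, but thinning hardly alters the expected fold change of well-read genes. It therefore cannot tell whether something that went with the deeper sequencing of KO replicates 2 and 3 took part. An effect of the genotype on either group of genes stays open.

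Eif4a2 (0.94, SE 0.12) and Rfc4 (0.94, SE 0.16), adjacent on chromosome 16 at 23107468 to 23114132 and 23113948 to 23127730, rose alike in KO cultures next to Adipoq (23146536 to 23157968), whose promoter drives the Cre, while Adipoq itself (0.47, adjusted p = 0.00632) and, named after their values were seen, Kng1 (0.65, adjusted p = 0.0286) rose and Kng2 (-0.50, adjusted p = 0.0164) and Rtp4 (-0.58, adjusted p = 0.0286) fell. Chance neighbours cannot be told apart from a joint rise, because the 63 genes risen as far were taken at the fold of Eif4a2 itself, so that 1 of their 2 adjacent pairs was counted by construction, and the other, Srp54b and Fam177a2, rests on copies (4% of 1000 random placements gave 2 pairs or more and 27% at least 1). Extra copies of this neighbourhood, as a large transgene could bring, cannot be told apart from other causes, because the excess of both genes over 3 flanking genes was 0.93 (SE 0.15) in culture and -0.19 (SE 0.13) in WAT, where the flanking gene St6gal1 itself rose (1.26, adjusted p = 0.00441). In WAT Eif4a2 was at 0.25 (adjusted p = 0.155) and Rfc4 at 0.26 (0.175). With library size only they were at 0.93 (0.00104) and 0.95 (0.00191), and the 3 flanking genes rose too. The exact two-sided permutation test of that excess gave p = 0.1 in culture, the smallest that 3 against 3 allow, and 0.3 in WAT, and setting the WAT value aside for St6gal1 was decided after it was seen. Shared reads cannot be told apart either, since the gene models overlap by 185 bases.

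For the 6 libraries of WAT and of culture there are 10 splits each, too few for a share under 0.05. Splits other than the real one also put the difference between genotypes into the spread within groups, which holds their gene counts down. The real split of WAT gave 8542 genes and 20 lists, as large in 1 split for both, and the other splits gave 0 genes (edgeR) and 7 to 18 lists. The real split of the cultures gave 2459 genes and 12 lists, again as large in 1 split, and the other splits gave 0 genes and 4 to 9 lists. Camera with the preset correlation thus passed many lists in splits that mix the genotypes. Such splits keep part of the genotype difference, since most libraries of a group share a genotype, so they do not give the number expected by chance. For genes changed the same way in both comparisons, 1 of 100 assignments reached 589, the real 1, and the highest other was 0. In all 99 others WAT or culture had 0 genes called, which fixes that count at 0, so these assignments cannot tell whether chance gave it and say nothing of shared responses. The 589 lay under the 703 for independent lists.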

How the results depend on the processing

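Library size only, the length and GC trend, thinning, summed copies, and removal of unnamed loci or mitochondrially encoded genes were chosen after the data were seen. In WAT, 74 of 92 named genes and 4 of 29 lists kept direction and side of the threshold in every alternative, an estimated correlation included, and in culture 12 of 70 genes and 7 of 28 lists did, with 57 genes lost in 1 fit over all 4 groups. That fit shares the wider spread of WAT, which raises the p-values in culture by construction. In WAT, where it can understate the spread, it called 9005 genes. The cause of the other changes was not tested. Changes of 2-fold were recovered for 13.4% of simulated genes in WAT and 85.1% in culture, and depth was not varied in that simulation.

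Fam50a in WAT (-0.60) was 0.089 with library size only and -0.26 with the length and GC trend removed. Without single libraries it ran from -0.81 to -0.44, with the call lost without WT replicate 1 (-0.59), 2 (-0.65) or 3 (-0.56) or cKO replicate 1 (-0.63). In culture (-0.26) it ran from -0.34 to -0.16, passed the threshold without WT replicate 3 (-0.34), and passed with the length and GC trend removed (-0.31).

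Changed genes in WAT (8542) ranged from 6456 to 10265 over alternatives without a fold minimum, and with at least 2-fold they were 5133, with 1975 lower. With library size only, 8838 were higher and 1427 lower, and of its 10265 calls 6075 were shared with TMM, 6022 with the same sign. With the length and GC trend removed 7396 genes changed in WAT, of which 6243 were shared with the 8542, 6184 with the same sign. In culture (2459) the count was 146 in 1 fit over all 4 groups (58 higher, 88 lower) and 188 with at least 2-fold (56 higher, 132 lower). Without single libraries it ran from 897 to 3380, with 399 to 1715 higher and 498 to 1665 lower. It was 1499 without WT replicate 1 (687 higher, 812 lower), 897 without WT replicate 2, 3380 without WT replicate 3, 1528 without KO replicate 1 (699 and 829) and 1511 without KO replicate 2 (664 and 847). Of the 2459 genes, 2322 were shared with DESeq2 and 1564 with the fit that removed the length and GC trend.

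With an estimated correlation camera called 0 lists in WAT and 0 in culture, against 2 and 1 at an unadjusted p under 0.05 and 18 and 13 by fry. The epithelial median in WAT (3.83) was -3.09 without cKO replicate 3 (adjusted p = 0.0296), in a range from -3.09 to 5.24, and -0.98 with the replicate block. Trp63 in culture (0.26) was -0.01 without WT replicate 1 and -0.080 without KO replicate 2, in a range from -0.080 to 0.48. Lists that passed without 1 library and not with all 6 were, in WAT, erythroid markers without cKO replicate 1 (-1.25, adjusted p = 0.0268), insulin signalling without cKO replicate 2 (-0.31, 0.0263) and factors that restrain adipogenesis without WT replicate 1 (0.97, 0.0471) or cKO replicate 2 (0.93, 0.0364). In culture they were cell division without WT replicate 2 (0.22, 0.0119) or KO replicate 3 (0.20, 0.0131), spliceosome genes without WT replicate 2 (0.074, 0.0449) or KO replicate 2 (0.11, 0.0492), lipid-laden macrophages without KO replicate 1 (-0.19, 0.0449), p53 targets without WT replicate 1 (-0.20, 0.0489), and lymphocyte (-0.95, 0.0492) and Schwann cell markers (-0.50, 0.0405) without KO replicate 2. With all 6 libraries and the length and GC trend removed, insulin signalling in WAT (-0.65, 0.00562) and factors that restrain adipogenesis (0.84, 0.02) passed, and in culture lipid-laden macrophages (-0.30, 4.1e-05), preadipocyte (-0.21, 0.00331), spliceosome (0.13, 0.0139), p53 (-0.14, 0.0324) and necroptosis lists (-0.15, 0.0388). By fry the factors that restrain adipogenesis passed in WAT (0.0127), and in culture the lymphocyte, necroptosis, p53, preadipocyte, spliceosome and pro-adipogenic lists did (0.0381 each). Without a count filter spliceosome (0.0288) and cell division lists (0.0297) passed in culture, the former also in 1 fit over all 4 groups (0.0264), and with library size only spliceosome genes passed in WAT (0.0339). Culture medians moved over 1.5 times without WT replicate 1 for adipocyte (0.19) and cholesterol genes (-0.083), without WT replicate 3 for lipogenesis (-0.17), without KO replicate 1 for thermogenic genes (0.17), and for insulin signalling without KO replicate 2 (-0.23) or 3 (-0.35).

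With library size only, 7331 genes were more positive and 1198 more negative in WAT than in culture. On that scale 559 genes changed the same way in both, 410 higher and 149 lower, and 1193 in opposite ways. Without single libraries, genes changed the same way in both (589) ran from 187 to 1036 (263 without WT culture replicate 1, 187 without WT replicate 2, 1036 without WT replicate 3, 381 without KO replicate 1, 333 without KO replicate 2). The counts for independent lists in these settings ran from 251 to 972. Genes changed in opposite ways (845) ran from 323 to 937, with 323 without WT replicate 2, 508 without KO replicate 1 and 554 without KO replicate 2.

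The labels number the replicates alike in every group but do not say that the numbers pair samples, and they were not taken to. Same-numbered libraries deviated together with correlations of -0.33, 0.03 and -0.23 in WAT and 0.18, 0.03 and 0.24 in culture. In culture, where these were all positive, a pairing stays open. KO culture replicate 2 correlated slightly better with WT replicate 3 (0.0333) than with its own number (0.0324). With the replicate block 3824 genes changed in culture (1816 higher, 2008 lower), among them all 2459, and 7258 in WAT, of which 7137 were shared. The interaction then gave 6668 genes and the overlap 798 changed the same way. Among named genes and lists the block ended the call for Myh1 in WAT only (3.49, adjusted p = 0.197).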

Other observations

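The families below, their example genes and their tests were chosen only after the data were seen, with camera adjusted over the 6 families of each comparison. Glycolysis genes fell in cKO WAT for 13 of 15 members and rose for 2, with a median of -1.74, or -1.06 with library size only (camera adjusted p = 9.9e-08, adjusted p = 0.237 with an estimated correlation). Eno1, enolase 1, was at -2.56 (SE 0.26), Pfkl at -2.37 (SE 0.26), Aldoa at -2.34 (SE 0.28), Pkm at -1.82 (SE 0.17) and Hk2 at -1.67 (SE 0.30), while Hk1 was at 0.53 (SE 0.15). Adipocyte genes outside the naming rule fell as well, such as Fasn (-5.04, SE 0.60), Acaca (-4.80, SE 0.47), Acly (-4.63, SE 0.45), Scd1 (-4.63, SE 0.53), Plin1 (-1.65, SE 0.32), Lep, which encodes leptin (-1.31, SE 0.19), and Pparg (-1.24, SE 0.19). Fabp4 (-0.87, SE 0.35, adjusted p = 0.0684) and Cd36 (0.41, SE 0.20, adjusted p = 0.127) did not pass. Proteasome subunits in WAT fell for 24 of 37 and rose for 1, with a median of -0.63 that was 0.05 with library size only (camera adjusted p = 6.0e-05, adjusted p = 0.792 with an estimated correlation).

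In KO cultures the same proteasome family rose for 17 of 37, with a median of 0.28 (camera adjusted p = 7.8e-08, adjusted p = 0.328 with an estimated correlation), among them Psmd6 (0.58, SE 0.11) and Psma1 (0.53, SE 0.11). Mitochondrially encoded genes rose for 8 of 13, with a median of 0.53 (camera adjusted p = 7.8e-08, adjusted p = 0.328 with an estimated correlation), and COX2 was at 2.05 (SE 0.26), COX3 at 1.83 (SE 0.29) and ATP6 at 1.30 (SE 0.25). Ribosomal protein genes rose for 13 of 79, with a median of 0.15 (camera adjusted p = 4.6e-06, adjusted p = 0.526 with an estimated correlation), and many have pseudogenes that share reads. Cathepsin genes fell for 6 of 11, with a median of -0.35 (camera adjusted p = 0.000672, adjusted p = 0.328 with an estimated correlation), with Ctsh at -0.83 (SE 0.11). These 4 medians were 0.23, 0.47, 0.099 and -0.41 with library size only. They were not computed with the length and GC trend removed, so a part of that trend in them was not tested.

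Other families gave no list call. In WAT these were ribosomal protein genes (6 of 79 higher and 8 lower, median -0.033, or 0.64 with library size only, camera adjusted p = 0.514), proton pump subunits (5 of 20 higher and 3 lower, median -0.00050, or 0.68 with library size only, 0.514), cathepsins (6 of 12 higher and 1 lower, 0.225) and major urinary protein genes (3 of 12 higher, 0.393), and in culture proton pump subunits (3 of 19 higher and 3 lower, median 0.0019, or -0.054 with library size only, 0.854) and glycolysis genes (1 of 15 lower, 0.265). Skeletal muscle transcripts differed between single WAT libraries of both genotypes, with Acta1 at 30.8, 149 and 470 CPM in WT and 480, 179 and 40.6 CPM in cKO replicates 1 to 3. Reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in all 12 libraries, and in cKO WAT these genes were higher by 0.75 (SE 0.18), 1.31 (SE 0.24), 1.31 (SE 0.31) and 0.85 (SE 0.24), with adjusted p from 0.00375 to 0.0212. In culture Uty (0.46, SE 0.14) and Kdm5d (0.50, SE 0.15) rose, and Ddx3y (0.35, SE 0.13, adjusted p = 0.0591) and Eif2s3y (0.30, SE 0.12, adjusted p = 0.0777) did not pass.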
